A study of Mus musculus with 6 samples.

How the data were processed

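Testis RNA of C57BL/6 mice was sequenced after 8 weeks on normal food or on high-fat food, with 3 libraries per diet. Per the labels' protocols, RNA was extracted with Trizol from 50 mg of tissue and made into strand-specific libraries by the dUTP method. Trimmomatic, HISAT2, StringTie, DESeq and the genome build GRCm38 are named in the submitters' processing notes, without versions. The labels do not state that each library came from its own animal, so p-values measure the spread between these libraries, which may be partly technical. The numbers of the libraries, 7 to 9 for the normal and 10 to 12 for the high-fat diet, are not shared between diets and pair nothing.

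The deposited comparison table has 1 line per transcript, not per gene. It holds estimated counts for each of the 6 libraries, per the file headers, and these are whole numbers as deposited. A second block of columns holds the same counts after scaling, rounded by the authors and treated here as a score only. A signal column holds the authors' mean of the scaled counts over all libraries and was not used in a test. The table also gives the authors' linear fold change (a ratio), log2 fold change, p-value and adjusted p-value. All 831 transcripts have an adjusted p under 0.05 in the authors' deposited table. From the ratio of adjusted to unadjusted p and the rank, the number of transcripts the authors tested came to 95751, so 94920 are not listed. This number followed from 730 lines to within 0.05 percent, 101 lines gave fewer and 0 gave more. The other 3 deposited tables hold set enrichment results, with the p-value and q-value of each set and the authors' mean normalized count of each member.

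Of the 831 transcripts, 433 carry an annotated transcript identifier and 398 were assembled by the authors from their reads. Of the assembled transcripts, 382 overlap a GENCODE M21 gene on the same strand and are named here by that gene; 107 of them overlap more than 1 gene and 16 overlap none, so these names are uncertain. Of the annotated transcripts, 431 are in GENCODE M21, 154 of them with identical coordinates. Coordinates are those of the deposited table. For 1 transcript the symbol had become a calendar date in the table and was read from GENCODE. All sample columns were used.

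Each library's size factor was recovered as its count over its scaled value at counts of at least 5000. The size factors were 0.940, 1.05 and 1.09 in the normal-diet libraries and 0.908, 0.999 and 1.14 in the high-fat libraries. The total counts of a whole library are not given in the sources used here; the listed transcripts sum to between 362790 and 490603 counts per library, which is part of the depth only. Normalized counts below are the deposited counts divided by these size factors, given as mean ± SD with n = 3. A fold against a diet with 0 counts in all 3 libraries is a lower bound against a floor of 3 counts per library. Floors and intervals of this kind cover counting error only.

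The counts were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, filterByExpr with its minimum count of 10), with Benjamini-Hochberg adjustment over the tested transcripts and a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. The test had been fixed with TMM normalization before the data were examined. TMM assumes that most transcripts do not differ, and a table that holds called transcripts alone does not meet this, so the authors' size factors were used in its place. That choice was made after the data were seen. TMM lowered the log2 fold changes by a median of 0.49 and called 646 transcripts, 340 higher and 306 lower, against 678, 379 higher and 299 lower, with the authors' size factors. Because every transcript had been listed for its difference between the same libraries, a test on this table is not an independent test of the diet, and its adjusted p-values do not account for the transcripts not listed. DESeq2 1.42.0 with the authors' dispersions and size factors gave all 819 transcripts with a deposited log2 fold change under 15 in size to within 0.05, and their p-values to within 1.25-fold. The other 12 transcripts have larger deposited fold changes.

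The edgeR step was tested on simulated data for the comparison of the diets, with 754 transcripts tested. At a simulated fold of 2 it recovered 13.6% of the changed transcripts, at 4 46.5%, at 8 68.1% and at 16 63%. It called 4 of 574 unchanged transcripts and gave no changed transcript the wrong direction. With adjustment over all 95751 transcripts it recovered 0 at each of these folds.

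A total of 41 gene lists was fixed before the data were examined, covering thermogenesis, the respiratory chain, metabolism, stress, germ cell stages, somatic cells and tissues that dissection can bring in. The tests camera and fry were not run on them, because each measured member had been listed for a difference and no unlisted background was used here. Members were counted by direction, as had been planned for a table holding part of the genes, and Fisher's exact test of direction against the rest of the table was added after the data were seen. Transcripts named in the text are the 12 largest rises and the 12 largest falls past the edgeR threshold whose 3 libraries of one diet all lay beyond the 3 of the other, with a mean of at least 10 counts, and up to 4 members of each list with the smallest p. Canonical coding transcripts with a mean of at least 1000 normalized counts, members of the deposited sets and the loci with several transcripts were chosen after their values were seen. Alternatives were limma-voom (limma 3.58.1), DESeq2, other scalings, other filters and thresholds, and the omission of each library. Counts and tables were handled with Python 3.11.15, scipy 1.17.1 and pandas 2.3.3.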

Results

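Testis RNA of mice fed high-fat food for 8 weeks was compared with that of mice fed normal food, with 3 strand-specific RNA-seq libraries per diet. The series title names thermogenesis pathways in obese mice as its subject. The values describe transcripts rather than genes, and the deposited table lists 831 that the authors called out of 95751 tested. The listed transcripts sum to 362790, 390717 and 402866 counts in the normal-diet libraries and to 427777, 438171 and 490603 counts in the high-fat libraries.

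In the authors' deposited table, 460 transcripts were higher and 371 lower on the high-fat diet. Among canonical coding transcripts at high counts, the mitochondrial complex III subunit Uqcrc1, the matrix protein Sparc, the collagen chain Col1a1 and the Golgi tethering subunit Cog4 were higher. The translation elongation factor subunit Eef1g, Zfp318 and Tbl3 were lower. These are examples, and some other transcripts of this kind changed more. Dennd4c rose from 396 ± 75.4 to 2643 ± 1210 normalized counts and Ccdc88a from 609 ± 246 to 3135 ± 1394, while Mycbpap fell from 4324 ± 1595 to 199 ± 191. Most of the largest differences belonged to transcripts assembled by the authors that had 0 counts in all 3 libraries of one diet, as the plot of the called transcripts shows. With edgeR on the listed counts, 678 of 680 tested transcripts had an adjusted p under 0.05, 379 higher and 299 lower. These transcripts had been listed for this same difference, so the count is not independent evidence. When the adjustment covered all 95751 transcripts, with unlisted ones ranked behind, edgeR called 1, although 678 had an unadjusted p under 0.05. On simulated counts that adjustment recovered 0 changed transcripts at folds of 2, 4, 8 and 16. Larger folds were not simulated, although 250 listed transcripts were at 0 in all 3 libraries of a diet. The simulation therefore cannot say what the adjustment would recover among such transcripts.

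**Figure D1:**
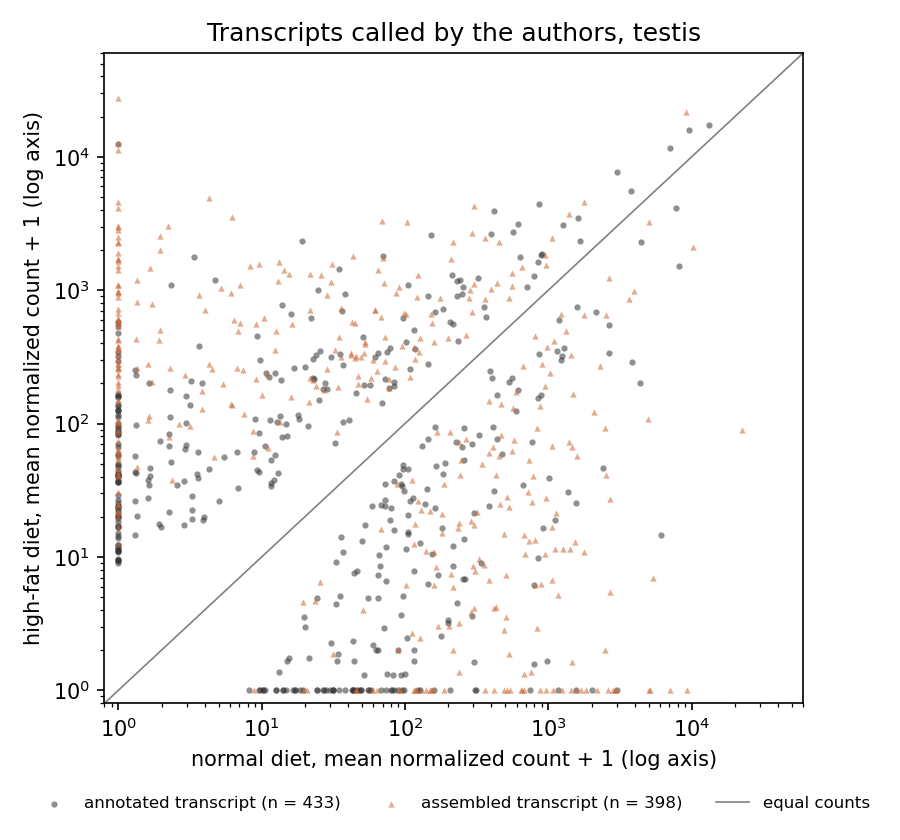
Mean normalized count plus 1 of each of the 831 called transcripts on the normal diet (horizontal, log axis) and the high-fat diet (vertical, log axis), n = 3 libraries each, with annotated (433) and assembled (398) transcripts as separate symbols and a line at equal counts. The points along the left and lower edges are the 150 transcripts at 0 in all normal-diet libraries and the 100 at 0 in all high-fat libraries.

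Sparc, ENSMUST00000018737 on chromosome 11 from 55394500 to 55420200, had 2991 ± 658 normalized counts (SD, n = 3) on the normal diet and 7752 ± 1174 on the high-fat diet, a log2 fold change of 1.37 ± 0.23 (SE; edgeR adjusted p = 0.00406). Col1a1, ENSMUST00000001547, rose from 1617 ± 269 to 3455 ± 519, a log2 fold change of 1.10 ± 0.23 (edgeR adjusted p = 0.00633), and this call was lost with TMM (edgeR adjusted p = 0.0508). Cog4, ENSMUST00000034203, rose from 1267 ± 238 to 3095 ± 541. Eef1g, ENSMUST00000052248 on chromosome 19 from 8967041 to 8978479, fell from 8200 ± 5587 to 1530 ± 82.9, and its normal-diet libraries ranged from 4084 to 15206 counts. Zfp318, ENSMUST00000113481, fell from 7788 ± 575 to 4097 ± 601 (edgeR adjusted p = 0.00458). Tbl3 fell from 3811 ± 82.9 to 289 ± 221. The canonical Fbxo3 transcript fell from 2645 ± 493 to 336 ± 122 while a transcript assembled at the same locus rose from 1387 ± 361 to 3702 ± 597, and their sum was 4032 ± 431 and 4037 ± 628 (edgeR adjusted p = 0.992). Stat4, ENSMUST00000027277, was at 3776 ± 195 and 5568 ± 199, and its edgeR call was lost with TMM (adjusted p = 0.686). It was also lost when any of normal-diet libraries 7, 8 and 9 or high-fat library 10 was left out. In these fits the edgeR adjusted p was between 0.0562 and 0.0833 and the log2 fold change between 0.528 and 0.601. The log2 fold change of Stat4 was 0.56 in the main fit and 0.065 with TMM.

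The 12 largest rises were transcripts assembled over Dnaaf1, Ncoa4, Sec23ip, Ppp2r2d, 2700049A03Rik, 1700010L04Rik, Polr2c, R3hdm2, Gm47362, Ndst1, Ak9 and Atp13a3. The transcript over Dnaaf1, a dynein assembly factor, spans 119575296 to 119601780 on chromosome 8. It had 0 counts in the normal-diet libraries and 27820 ± 7118 normalized counts on the high-fat diet, at least 9472-fold higher. The transcript over Ncoa4, a ferritin cargo receptor, reached 3020 ± 831, at least 1028-fold higher. At the Polr2c locus the canonical transcript fell from 2159 ± 244 to 687 ± 105, and the sum of both did not pass the test (edgeR adjusted p = 0.560). Among the 12 largest falls were transcripts over Piwil2, Agbl5, Col20a1, Tdrd12, Msl2, Cramp1l, Cluh, Kmt2d, Klhl24 and Larp1, and the annotated transcripts ENSMUST00000229585 of Col22a1 and ENSMUST00000194706 of Gm7292. The one over Tdrd12, a gene of the piRNA pathway, was at 2612 ± 458 on the normal diet and at 0 in the high-fat libraries, at least 876-fold lower. The one over Piwil2 was at 120, 2018 and 7317 counts on the normal diet. Those over Kmt2d and Klhl24 were also uneven there, at 2733, 43 and 293 and at 1960, 115 and 738 counts. Among the rises, the transcript over 2700049A03Rik was at 1094, 5462 and 58 counts in the high-fat libraries. The means and ranks of such transcripts depend on single libraries. The transcripts named here by Tdrd12, Piwil2, Col20a1, 1700010L04Rik, Ak9 and Gm47362 each overlap more than 1 gene, so these names are uncertain. The loci of 1700010L04Rik, R3hdm2, Atp13a3 and Gm7292 also held called transcripts of the opposite direction, and their sums did not pass the test (edgeR adjusted p = 0.282, 0.711, 0.0655 and 0.909). At the locus of 1700010L04Rik, the opposite transcript was named for another gene, Mex3b. These values concern single transcript models and not the total output of the genes.

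The authors' deposited enrichment tables hold a thermogenesis set with 8 called members, all higher on the high-fat diet, with p = 0.00781 and q = 0.915. A Wilcoxon signed-rank test over the 8 members gave the same p, so its units were genes called beforehand and not libraries. Any 8 members of the same direction give this p, so it does not test the diet. The members were transcripts of Uqcrc1, Gnas, Smarca2, Dpf1, Creb1, Atp5pb, Rps6kb2 and Adcy3. Each carries the same symbol in mouse and human, but other human symbols that the authors paired look like other genes, such as ZFP14 for Zfp184 and SLC26A2 for A26c2, so p and q of the deposited sets may be affected. The study chose this set on the same libraries, so it is not independent evidence of the direction. Uqcrc1, ENSMUST00000026743 on chromosome 9 from 108936633 to 108949624, was the only canonical transcript among them. It had 9611 ± 713 normalized counts (SD, n = 3) on the normal diet and 15865 ± 411 on the high-fat diet, a log2 fold change of 0.72 ± 0.10 (SE; edgeR adjusted p = 0.00294). With TMM, the normalization planned at the outset, its log2 fold change was 0.23 and the call was lost (edgeR adjusted p = 0.0958).

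The other members were less abundant alternative transcripts. A transcript of Gnas, which encodes the stimulatory G protein subunit, rose from 2.35 ± 1.71 to 1781 ± 1189. One of Creb1, a cAMP-responsive transcription factor, rose from 26.6 ± 0.975 to 201 ± 51.9, a log2 fold change of 2.91 ± 0.37 (edgeR adjusted p = 0.00269). Transcripts of the chromatin remodelling subunits Smarca2 and Dpf1 rose from 64.0 ± 18.2 to 337 ± 154 and from 0.307 ± 0.532 to 252 ± 127. The Atp5pb transcript, annotated as a target of nonsense-mediated decay, rose from 1.29 ± 0.486 to 112 ± 40.6. Those of Rps6kb2 and Adcy3 were called by the authors and fell below the edgeR count filter, at 8, 83 and 113 and at 17, 95 and 6 counts in the high-fat libraries. Thus 6 of the 8 were tested with edgeR, and 6 passed. Of the genes fixed in advance for lookup, Ucp1, Ucp2, Ucp3, Ppargc1a, Star, Cyp17a1, Lep and Adipoq, 0 had a listed transcript.

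**Figure D2:**
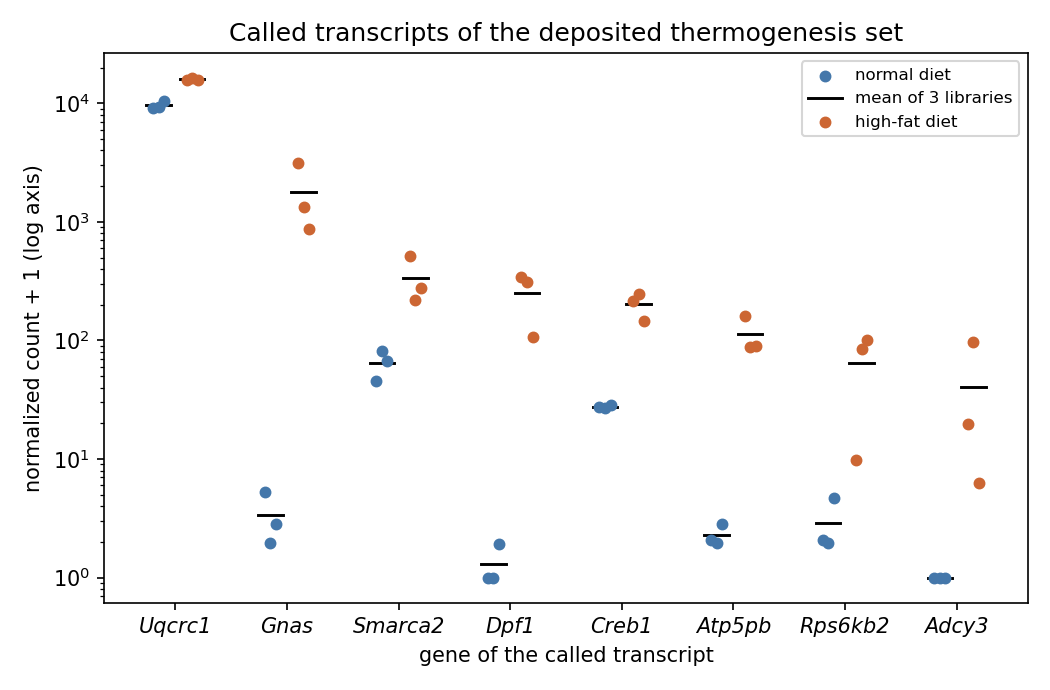
Normalized count plus 1 (vertical, log axis) of the called transcript of each of the 8 genes of the deposited thermogenesis set, with 1 point per library, 3 per diet, and a bar at the mean. The high-fat libraries lie above the normal-diet libraries for each transcript, from 15865 against 9611 on average for Uqcrc1 to 39.7 against 0 for Adcy3.

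A set of cellular responses to external stimuli had 8 members, all lower, with p = 0.00781 and q = 0.915 in the authors' deposited table. The canonical transcript among them, of the mitochondrial ribosomal protein Mrpl18, fell from 434 ± 122 to 163 ± 32.8 (edgeR adjusted p = 0.0124). The Fos member was the noncoding transcript ENSMUST00000136122, at 76, 42 and 26 counts on the normal diet and 0 on the high-fat diet. The canonical Fos transcript ENSMUST00000021674 went the other way, from 0 in each normal-diet library to 11, 25 and 21 counts. The Golgi vesicle transport set had 12 of 13 members higher and the lowest q of the 35 deposited sets, 0.119. It included Cog4 and the COPII coat subunit Sec23b, whose canonical transcript rose from 320 ± 72.0 to 1233 ± 227 (edgeR adjusted p = 0.00427). A transcript assembled at the Sec23b locus fell from 428 ± 175 to 40.1 ± 12.4, and their sum rose from 748 ± 120 to 1274 ± 215 (edgeR adjusted p = 0.0375). In the authors' deposited tables, 0 of the 35 sets had a q under 0.05. All 35 had a p under 0.01, the highest being 0.00847, and among the 20 network neighbourhoods the highest was 0.000942. These tables may therefore list only sets of low p, by a rule that may differ between them. Of the 35, 34 had more members higher than lower, in a comparison table where 202 of 370 human symbols (54.6%) were higher. If the sets were listed by their p, these counts describe the listed sets only.

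Of the 41 lists, 19 held a called annotated transcript and 22 held none, among them the lists of fatty acid oxidation, cholesterol synthesis, inflammation, the unfolded protein response, macrophages, lymphocytes, blood, epididymis and endothelium. The table leaves out uncalled transcripts, so their levels were not analysed here. In total 31 annotated transcripts of listed genes were called by the authors, 20 higher and 11 lower; 25 of them passed edgeR. Signalling genes of thermogenesis had 4 members higher and 0 lower (Fisher's exact test of direction against the rest of the table, two-sided p = 0.129); 2 of these were tested with edgeR, and 2 passed when adjusted over the list alone, which is not independent evidence. This was the only list with 3 or more annotated genes. Of the thermogenic programme list, 0 annotated transcripts were called; assembled transcripts over Zfp516 and Adrb1 were called higher and lower.

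Germ cell genes moved in both directions. The cohesin subunit Stag3 of meiotic cells had 2 lower annotated transcripts, of which ENSMUST00000161113, with a retained intron, fell from 4458 ± 204 to 2291 ± 352 (edgeR adjusted p = 0.00553). All 4 called transcripts of the Stag3 locus were lower, and their sum fell from 12325 ± 3170 to 4138 ± 109 (edgeR adjusted p = 0.0033). A transcript of the mismatch repair gene Mlh3 rose from 1.27 ± 2.20 to 67.3 ± 30.8. The canonical transcript of the sperm fibrous sheath gene Ropn1 rose from 7100 ± 698 to 11660 ± 1282, and ENSMUST00000148562 of the same gene fell from 6115 ± 694 to 13.6 ± 2.03. The Ropn1 rise was lost with TMM (edgeR adjusted p = 0.189). Among somatic genes, a transcript of the steroidogenic enzyme Hsd3b6 was at 1590, 1722 and 8 counts on the normal diet and at 15, 33 and 5 on the high-fat diet (edgeR adjusted p = 0.0223). That call was lost when any of normal-diet libraries 7 and 8 or high-fat libraries 10, 11 and 12 was left out, with edgeR adjusted p between 0.0521 and 0.0788. The log2 fold change was between -5.48 and -6.728 in these fits, against -5.945 in the main fit. With limma-voom it was -4.2 and the call was lost as well (limma-voom adjusted p = 0.24).

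Called transcripts of opposite direction were found at 37 loci. Their summed counts passed edgeR at 7 of these, 5 higher and 2 lower, and did not at 30. Here and above, a sum covers only the called transcripts of a locus. Unlisted transcripts of the locus are left out, so a sum is not its total output. Some of the 37 loci pool transcripts named for different genes. These are the loci of 1810009A15Rik and Ganab, Gm44020 and Rps4l, Leng8 and Ttyh1, 1700010L04Rik and Mex3b, and Gm9625 and Zfp493. The sum at Gm41109 rose from 1163 ± 179 to 4408 ± 660 (edgeR adjusted p = 0.0028), and that at Leng8 and Ttyh1 fell from 1049 ± 143 to 107 ± 32.6 (edgeR adjusted p = 0.0028). The canonical Pdgfrb transcript was at 0 in the normal-diet libraries and at 296, 273 and 318 counts in the high-fat libraries, while ENSMUST00000115274 was at 323, 312 and 260 and then at 0, 0 and 9 counts. Summed over both, Pdgfrb had 293 ± 52.0 and 295 ± 27.3 normalized counts (edgeR adjusted p = 0.976). The summed Ropn1 transcripts had 13576 ± 1094 and 14145 ± 1773 (edgeR adjusted p = 0.687). The sums of Slc52a2 and Mtmr9 likewise did not pass the test (edgeR adjusted p = 0.630 and 0.527). The loci named here were chosen after their values were seen.

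**Figure D3:**
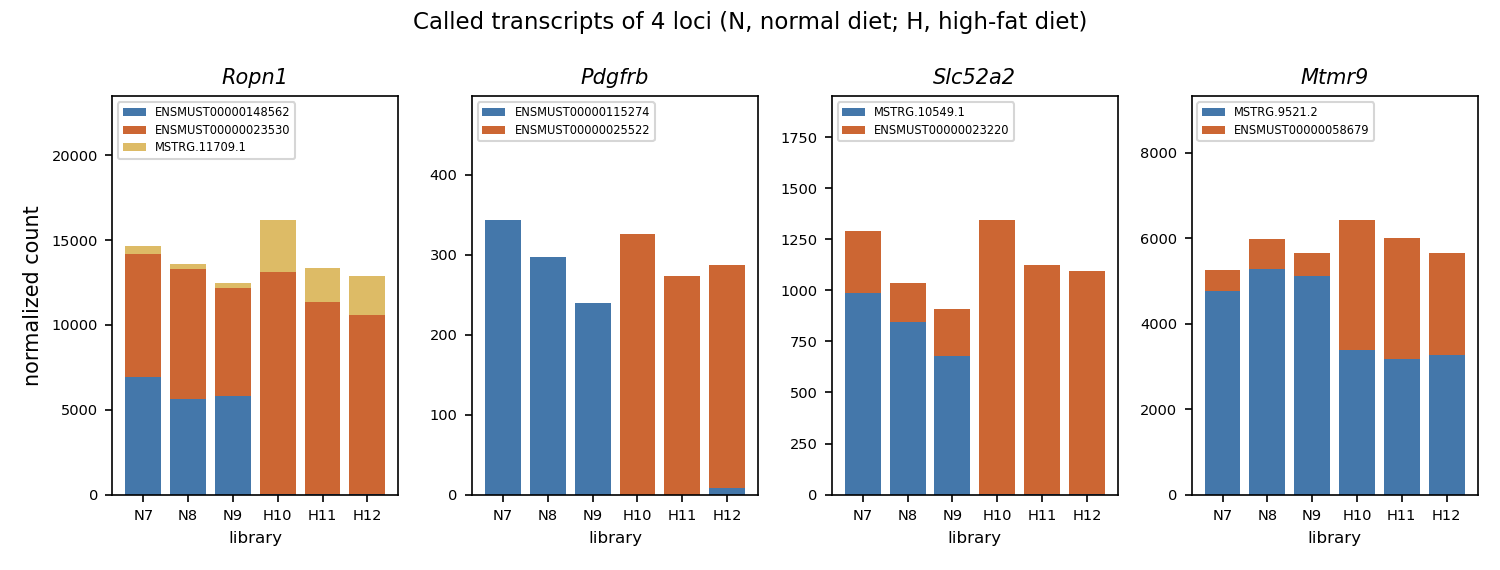
Stacked normalized counts (vertical, linear axes from 0) of the called transcripts of Ropn1, Pdgfrb, Slc52a2 and Mtmr9 in each library (horizontal), with 1 colour per transcript and N and H for the normal and high-fat diet. For Pdgfrb the stacks average 293 on the normal and 295 on the high-fat diet while the transcript that fills them differs.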

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

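Chosen after the data were seen were the scaling by the authors' size factors, the adjustment over all tested transcripts, the summing per locus, the addition of assembled transcripts, the omission of transcripts that flip between 0 and 100 within a diet, the restrictions to annotated or canonical transcripts, and the counts of set members. The edgeR count of 678 calls became 1 when adjusted over all transcripts the authors tested. Unlisted transcripts were ranked behind, so these adjusted p-values are upper limits for the p-values of this fit. The fit used the listed transcripts alone, and a fit on all transcripts could give larger or smaller p-values. The number of tests alone does not account for the drop, since the authors' p-values adjusted over that number kept all 831 calls. edgeR gave larger p-values, such as 5.13e-06 against 6.39e-40 in the authors' deposited table for the transcript over Dnaaf1. The adjustment over all transcripts also left 0 of 6 thermogenesis members, 0 of 6 external stimuli members, 0 of 10 Golgi transport members and 1 of 25 listed annotated transcripts. Other settings gave 582 to 822 calls (limma-voom 633, TMM 646, DESeq2 size factors 628, library totals 666), and 576 of 608 loci were called when counts were summed per locus. DESeq2 called all 831, which is no check because DESeq made the list. Leaving out 1 library gave 687 to 714 calls among 764 to 774 tested transcripts, against 678 of 680 in the main fit. The share of tested transcripts called was therefore lower in each of these fits. With an adjusted p under 0.01, 531 of the authors' 831 calls stood, 302 higher and 229 lower. Separately, 433 of all 831 calls were annotated transcripts, 235 higher and 198 lower. With canonical transcripts only, 1 thermogenesis, 1 external stimuli and 3 Golgi transport members passed. With a mean count of at least 50, 3 external stimuli members passed, because fewer were tested. Adding assembled transcripts by overlapping gene raised the listed transcripts called from 25 to 51. The deposited sets with a q under 0.05 and under 0.01 both numbered 0. Of 64 named transcripts with an edgeR fit, 0 changed direction; 9 lost their call under an alternative other than the adjustment over all transcripts, among them Uqcrc1, Stat4, Ropn1, Col1a1, Colgalt1, Nsmaf and Rabgap1 with TMM. The log2 fold changes of those lost with TMM each fell by about the median shift of 0.49 that TMM puts on this table. That of Uqcrc1 went from 0.723 to 0.228 and that of Col1a1 from 1.096 to 0.596. The cause was not tested beyond this shift. The planned camera and fry tests and their alternatives were not run, and no pseudocount was varied. The size of a log2 fold change against 0 counts is not fixed by the data. For the transcript over Dnaaf1 it was 17.8 with edgeR and 17.2 in the authors' deposited table. No paired analysis was possible because the diets share no replicate numbers. The depth of whole libraries was not analysed here.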

Other observations

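The tests in this part were chosen after the results were seen, except the covariance test at loci, whose outcome was stated before it was computed. Annotated transcripts with a retained intron were lower more often than the rest of the annotated transcripts, with 15 higher and 32 lower against 220 higher and 166 lower (Fisher's exact test, two-sided p = 0.0017, adjusted p = 0.0084 over 5 kinds of transcript). They included Dusp1, which fell from 104 ± 5.45 to 14.3 ± 9.91 normalized counts, and Rpl10a, which fell from 97.9 ± 31.0 to 30.4 ± 8.26, while that of Rpl41 rose from 10.2 ± 2.57 to 223 ± 95.8. Coding transcripts had 168 higher and 115 lower (p = 0.0045, adjusted p = 0.0112 by the same exact test). Transcripts are not independent replicates, so these values describe the table.

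Over the 10 thermogenesis and respiratory chain lists joined, 9 annotated transcripts were higher and 0 lower (Fisher's exact test, two-sided p = 0.0046). The lists were joined after their members had been seen and the study named this theme on the same libraries, so the p-value is not independent evidence. With assembled transcripts added, 11 were higher and 2 lower (p = 0.0459 by the same exact test).

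At 37 of 64 loci with several called transcripts, the transcripts moved in opposite directions, which was not beyond chance (35.2 on average with shuffled directions, and 37.2% of shuffles gave as many). The summed counts passed edgeR at 7 of the 37 loci. Whether the total output of the locus changes stays open, because the sums leave out unlisted transcripts of a locus. Sums of rising and falling parts also tend to change less than their members even in random pairs. Some of the 37 loci pool transcripts named for different genes, so not all of them hold models of 1 gene. A candidate explanation is that counts pass between transcript models of a locus. Random pairing of rising and falling parts gave a larger change of the sum (median 1.177 against 0.389, permutation p = 0.0001, the smallest the 10000 pairings can give), but pairing among loci of like expression gave 0.498 (permutation p = 0.052). Within diets the rising and falling parts varied against each other at 20 loci and together at 13 (exact binomial test, two-sided p = 0.296), so the explanation cannot be told apart from chance with 3 libraries per diet, and a switch of isoform with diet stays open.

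A total of 30 transcripts had 0 counts in 1 library and at least 100 in another of the same diet, such as the Ttbk1 transcript ENSMUST00000047034, at 0, 20147 and 19348 counts in the high-fat libraries. A single aberrant library is argued against as the cause of all 30, since 12 were in the normal diet and 18 in the high-fat diet and no library held the 0 for more than 9. High-fat library 10 held it for 9 of the 18, against 5 and 4 for libraries 11 and 12. Whether the reads went to other transcript models was not tested, because unlisted transcripts were not analysed here. A log2 fold change over 15 in size stood in the authors' deposited table for 12 transcripts, and 11 of them were of this kind.

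The real split of the 6 libraries by diet called 678 of the listed transcripts with edgeR, and the highest of the other splits called 0. Of the 10 possible splits 1 gave as many, the real one, and 3 libraries against 3 are too few for a share under 0.05; the transcripts had also been listed for the real split. In all, 759 of the 831 transcripts (91.3%) had non-overlapping diets, where chance gives 10%, but they had been selected for that difference.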
